A study of Homo sapiens with 6 samples.

How the data were processed

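Messenger RNA was measured in fibroblast-like synoviocytes, the fibroblasts of the joint lining, which per the labels' protocols were grown as primary lines from patients with rheumatoid arthritis. Per the labels' protocols the cells were transfected with a commercial pool of small interfering RNAs (siRNAs) against NUSAP1 or with a non-coding control, and were cultured further before any assay. RNA was selected by its poly-A tail and sequenced from both ends, per the labels' protocols. The labels' protocols describe both a directional and a non-directional library, and which was used is not given in the sources used here. Samples were grouped by their treatment label, with the letter from their title, into 3 control libraries (siCTL a, b and c) and 3 knockdown libraries (siNUSAP a, b and c). The labels do not say whether libraries of a group came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

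The deposited values are FPKM, fragments scaled to gene length and to the counted fragments of the library, with 1 value per Ensembl gene ID and library. The submitters' processing notes name CASAVA and the genome build hg19. The aligner, the counting tool, the annotation release, the use of strand and the siRNA sequences are not given in the sources used here. The table held 57905 gene IDs, of which 52338 matched the gene names and types of GENCODE 29. GENCODE 29 is drawn on another genome build than the authors' values, so it served only for names, gene types, chromosomes and transcript sequences, and no coordinates are given. XIST, TSIX and Y-linked genes, 474 IDs, were left out of every table and test.

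Within a library the FPKM values of a gene were whole multiples of 1 step, which gave each library's number of counted fragments and each gene's length. All 27460 genes above 0 in at least 1 library gave whole fragment counts in all 6 libraries, within a tolerance of 0.002. The recovered depth was 23609941, 25163811 and 20844651 fragments in siCTL a, b and c, and 21812390, 24217265 and 24710248 in siNUSAP a, b and c. The recovered counts summed to 99.74% of that depth in each library.

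Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 12873 in all. The groups were compared with limma on log2(FPKM + 1), with an intensity trend and Benjamini-Hochberg adjustment over all genes tested, and a gene was called changed at an adjusted p under 0.05. Fold changes are siNUSAP against siCTL on the log2(FPKM + 1) scale, which understates the change of low genes. The targeted gene was also compared by a 2-sided exact permutation test of FPKM. Gene lists, 38 in all, were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, which held for 32 lists, with Benjamini-Hochberg adjustment over the lists. The results of 1 list and of some single genes are not reported here. Calls of list members are given over all genes tested and adjusted over the list alone. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

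The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names NUSAP1, and the 10 rising and 10 falling protein-coding genes with the largest change among those with an adjusted p under 0.05, a mean FPKM of at least 2 and groups that did not overlap. It also names up to 3 members with the smallest p of each list that was called or had at least 3 changed members, and up to 1 member of each other list. The rule gave 117 genes, of which 46 were higher in siNUSAP, 68 were lower and 3 did not pass. MDM2, CDK4, CDK6, CCND2, MYC, FAP, MMP1, MMP2, MMP14, COL1A1, COL1A2, COL3A1, FN1, IL6, CXCL8, PTGS2, THY1, CXCL12, RPL7, TUBB, TUBA1B, ETV1, MAPRE2, CSF1, CDKN2B, DKK1, ROBO4, CD14, DNAJB9, HERPUD1 and PFKP fall outside the rule and were chosen after their values were seen.

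The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at an FPKM of 5, FPKM rescaled by the median ratio or to a fixed sum per library, quantile normalization, limma without a trend or with robust moderation, protein-coding genes alone, the replicate letters as a block, each library left out in turn, array weights, limma-voom on the recovered counts, camera with an estimated correlation, and fry. Removal of a cubic trend on gene length and GC content from each library, alone and with the block, was added after the data were seen. Counts of list members without siCTL c were added then too.

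Words of 7 bases in 3' untranslated regions (3' UTRs) were tested against the fold changes of 11155 of the 11309 tested protein-coding genes outside the mitosis, DNA replication and DNA repair lists (98.6%). These were the genes with an annotated 3' UTR of at least 50 bases. Each of 15781 words present in at least 100 of them was fitted by least squares with 3' UTR length, 3' UTR GC content and transcript length, on fold changes limited to 1 log2 unit either way. The most extreme word was set against the most extreme word in 100 shuffles of the residuals among genes. This test was added after the fold changes were seen.

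The steps were tested on simulated data. Drawn from the means and depths of these libraries for siNUSAP against siCTL, 50 of 12873 genes were changed at each of several sizes, and limma called 38% of those changed 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 9 of 12673 unchanged genes. With no gene changed it called 2. Camera called 10 of 10 lists of 20 genes changed 1.25-fold and 0 of 30 others, with the preset and with the estimated correlation. Changed genes and list members were taken from genes with a mean above 50 fragments, so the rates do not cover lower genes. No library was simulated to differ from its group. Genes were drawn independently of one another, with the same spread for all. These counts therefore do not cover lists whose members vary together, such as ribosomal protein genes (estimated correlation 0.8245). The word test found 6 of 6 planted words with an effect of -0.12 log2 units and 0 unrelated words.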

Results

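Gene expression was compared between RA synovial fibroblasts transfected with siRNA against NUSAP1, a microtubule-binding protein of the mitotic spindle, and the same kind of cells given a control siRNA. The study asked what loss of NUSAP1 does to invasion, migration, proliferation and adhesion of these cells, and the RNA libraries give the transcripts that go with it. There were 3 siCTL and 3 siNUSAP libraries, with 20844651 to 25163811 counted fragments each.

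NUSAP1 (ENSG00000137804, chromosome 15) stood at 28.1, 31.3 and 25.9 FPKM in siCTL a, b and c and at 0.0655, 0.413 and 0.145 FPKM in siNUSAP a, b and c. These values rest on 928, 1102 and 756 fragments in the control libraries and on 2, 14 and 5 in the knockdown libraries. The mean fell from 28.4 ± 2.71 to 0.208 ± 0.182 FPKM (SD, n = 3 each; 2-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The siNUSAP mean was 0.731% of the siCTL mean. The log2 fold change was -4.61 (SE 0.13; limma, Benjamini-Hochberg adjusted p = 4.13e-08), and every library matched its label.

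Of 12873 genes tested, 1840 were higher and 2019 were lower in siNUSAP (limma, adjusted p under 0.05). Large changes were mostly falls: 395 genes fell and 16 rose at least 2-fold. Without siNUSAP a and without siNUSAP c the higher genes numbered 1223 and 1175, and without siCTL a and without siCTL b those at least 2-fold higher numbered 25 and 31. The genes with the largest falls after NUSAP1 were the proliferation antigen MKI67 (log2 fold change -4.30), the DNA topoisomerase TOP2A (-4.11), the cytokinesis scaffold ANLN (-3.86), the spindle motors KIFC1 (-3.84) and KIF20A (-3.74), CDC20 (-3.79) and UBE2C (-3.72) of the anaphase-promoting pathway, the ribonucleotide reductase subunit RRM2 (-3.78), the kinetochore protein CENPF (-3.76) and the mitotic kinase PLK1 (-3.70). TOP2A fell from 205 ± 7.89 to 10.9 ± 0.705 FPKM (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 3.42e-09). RRM2 fell from 121 ± 2.94 to 7.85 ± 0.0588 FPKM (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 3.42e-09).

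Among protein-coding genes with a mean FPKM of at least 2, those with the largest rises changed far less. TSPAN2 also rose by 1.18, at a mean of 1.64 FPKM. PSKH1, a serine kinase, rose from 16.1 ± 1.26 to 38.2 ± 1.24 FPKM (SD, n = 3 each; log2 fold change 1.20, SE 0.07; limma, Benjamini-Hochberg adjusted p = 3.99e-06). TNFRSF10D, a decoy receptor for the death ligand TRAIL, rose by 0.97 log2 units to 43.1 ± 0.719 FPKM, and PTPN22, a tyrosine phosphatase, rose by 1.02 to 6.42 ± 0.472 FPKM. HHAT, which attaches palmitate to Hedgehog proteins, rose by 0.98, the growth factor FGF18 by 0.95, the ubiquitin ligase adaptor KLHL24 by 1.02, the gasdermin GSDMC by 1.05 and VWA5A by 0.96. Values of 1.13 for EVI2A and 1.11 for the cystatin CST2 are uncertain. EVI2A lies inside an intron of NF1, and CST2 has near-identical family members whose reads may have been counted with its own, which was not tested.

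**Figure D1:**
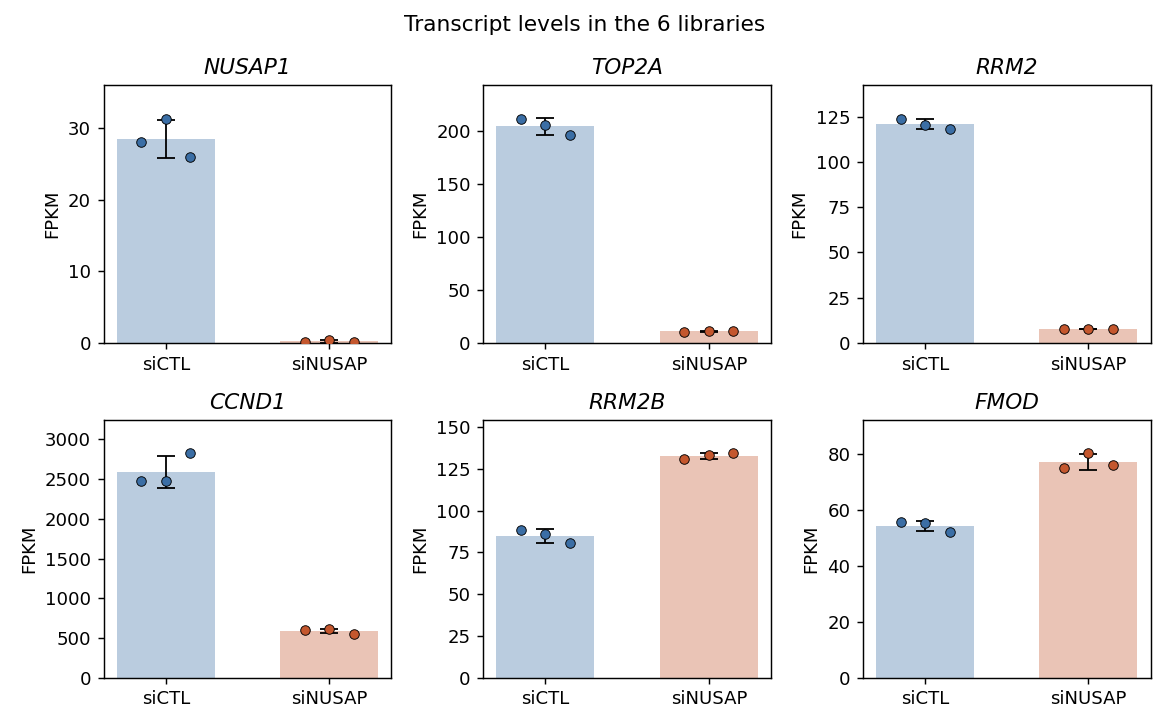
FPKM of NUSAP1, TOP2A, RRM2, CCND1, RRM2B and FMOD in siCTL and siNUSAP libraries; points are the 3 libraries of a group, bars their mean and error bars the SD. NUSAP1 lies between 25.9 and 31.3 FPKM in siCTL and at 0.413 FPKM or below in siNUSAP, and the groups do not overlap for any of the 6 genes.

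The cell division programme fell as a whole. All 35 mitosis genes fell, with a median log2 fold change of -3.26 (camera, Benjamini-Hochberg adjusted p = 9.46e-46); PRC1, which bundles spindle microtubules, went from 70.0 ± 1.93 to 5.19 ± 0.351 FPKM (SD, n = 3 each). All 24 tested DNA replication genes fell, with a median of -2.02 (camera, Benjamini-Hochberg adjusted p = 7.03e-29). Among them the origin licensing factor CDC6 fell by 2.48 and the helicase subunit MCM2 fell by 2.29 log2 units. Of 25 DNA repair genes 20 fell, none rose and 5 did not pass (median -1.69; camera, Benjamini-Hochberg adjusted p = 1.97e-17). FANCI (-2.55) and FANCD2 (-2.42) of the Fanconi anaemia pathway and the exonuclease EXO1 (-3.11) led this list. Adjusted over the list alone, 35 mitosis, 24 replication and 21 repair genes fell. These calls held with an estimated correlation, with an adjusted p = 0.00655 for each of the lists, the highest over the alternatives (camera, Benjamini-Hochberg).

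Several oncogene and tumour suppressor genes fell. CCND1, the cyclin that drives entry into S phase, fell from 2594 ± 201 to 587 ± 29.8 FPKM (SD, n = 3 each; log2 fold change -2.14, SE 0.07; limma, Benjamini-Hochberg adjusted p = 9.58e-08), and its 3' UTR holds the word ACACACA at 4 places. BRCA1 (-2.33) and BRCA2 (-1.98), which serve homologous repair, fell, as did the cyclin-dependent kinases CDK6 (-1.08) and CDK4 (-0.92) and the cyclin CCND2 (-1.11). Of 35 oncogene and tumour suppressor genes 16 fell, 1 rose and 18 did not pass, and adjusted over the list alone 18 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 1.36e-06). That call was lost at an adjusted p = 0.114 with an estimated correlation, in a range of 1.07e-09 to 0.114 over the alternatives (camera, Benjamini-Hochberg). ETV1 was the member that rose (0.40). MYC fell by 0.27 log2 units, and was not called without siNUSAP c (limma, Benjamini-Hochberg adjusted p = 0.0542, the highest over the alternatives).

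Genes induced by the tumour suppressor p53 were mostly higher. Of 20 tested, 13 rose, 1 fell and 6 did not pass, and 15 rose and 1 fell adjusted over the list alone (median 0.33; camera, Benjamini-Hochberg adjusted p = 2.61e-05). The call was lost at an adjusted p = 0.161 with an estimated correlation, in a range of 2.08e-08 to 0.161 over the alternatives (camera, Benjamini-Hochberg). RRM2B, the p53-inducible ribonucleotide reductase subunit, rose from 84.9 ± 4.13 to 133 ± 1.68 FPKM (SD, n = 3 each). The TRAIL receptor TNFRSF10B rose by 0.61, the stress protein SESN1 by 0.81 and the cyclin-dependent kinase inhibitor CDKN1A by 0.37 log2 units. MDM2, which targets p53 for degradation and is itself induced by it, was the member that fell (-0.22). Its call was lost with the length and GC trend removed (limma, Benjamini-Hochberg adjusted p = 0.0925), with no filter (0.082), with no trend (0.0711), with quantile normalization (0.0537), and without siCTL a (0.0683), siNUSAP a (0.114), b (0.0893) or c (0.0619), in a range of 0.0264 to 0.114 over the alternatives.

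Apoptosis regulators moved both ways. Of 21 BCL2 family and caspase genes 5 rose, 4 fell and 12 did not pass, and adjusted over the list alone 6 rose and 4 fell (camera, Benjamini-Hochberg adjusted p = 0.654). Among survival genes, BCL2 fell from 3.56 ± 0.379 to 0.909 ± 0.054 FPKM and BCL2L2 fell by 0.41 log2 units, while BCL2L1 rose by 0.44 (SD, n = 3 each).

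Microtubule genes were lower. Of 23 tubulin and microtubule genes 14 fell, 1 rose and 8 did not pass, with the same counts adjusted over the list alone (median -0.39; camera, Benjamini-Hochberg adjusted p = 4.33e-07). This call held at an adjusted p = 0.0382 with an estimated correlation, in a range of 9.25e-10 to 0.0382 over the alternatives (camera, Benjamini-Hochberg). The plus-end binding protein MAPRE1 fell from 51.7 ± 2.44 to 14.7 ± 0.822 FPKM (SD, n = 3 each) and holds CAGTACC in its 3' UTR, and the microtubule destabiliser STMN1 fell by 2.18 log2 units. Falls of TUBB6 (-0.79), TUBB (-0.69) and TUBA1B (-0.54) are uncertain as single genes because tubulins share reads. The end-binding protein MAPRE2 rose by 0.33, and was not called with no filter (limma, Benjamini-Hochberg adjusted p = 0.0729) or without siCTL a (0.061), siNUSAP a (0.0629) or siNUSAP b (0.0681), in a range of 0.00515 to 0.0729 over the alternatives. As single genes, the formin DIAPH3 (-2.67), the actin monomer binder PFN1 (-0.85) and the membrane linker EZR (-0.64) fell too, and the 3' UTRs of PFN1 and EZR hold ACACACA.

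**Figure D2:**
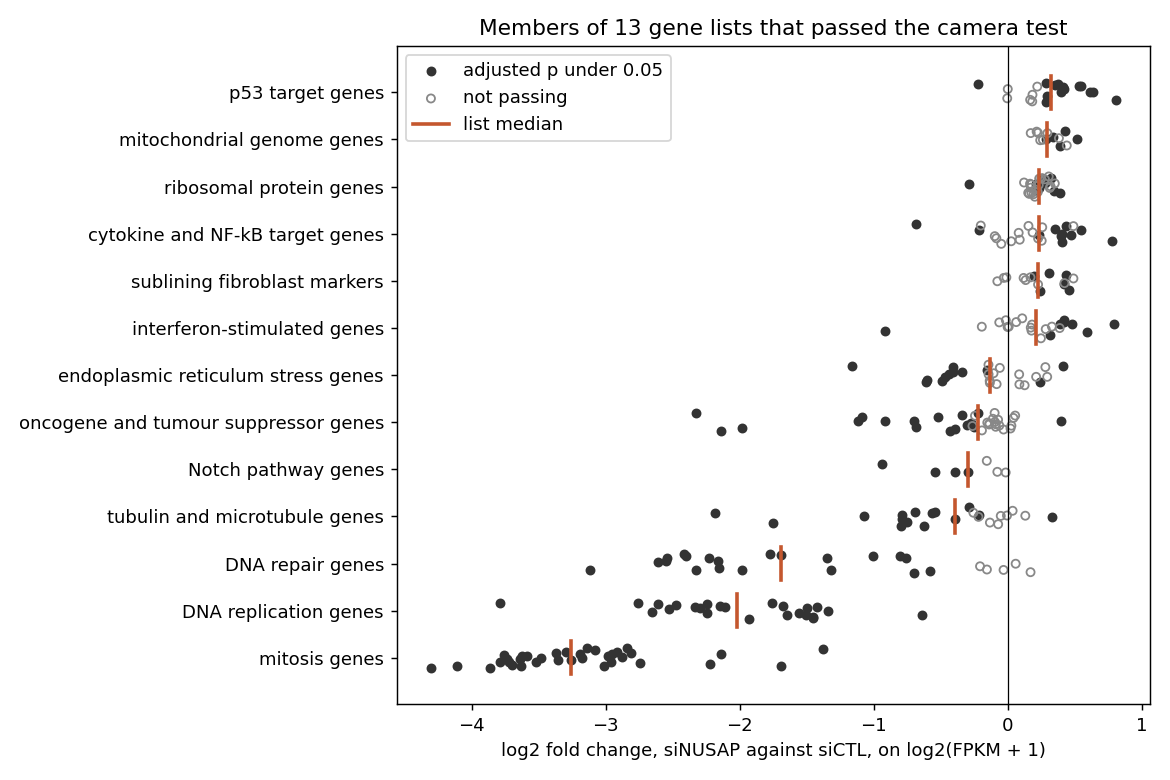
Log2 fold change of each tested member of 13 lists that passed camera, with siNUSAP against siCTL on the horizontal axis; filled points passed limma at an adjusted p under 0.05, open points did not, and the orange line is the list median. Mitosis genes have a median of -3.26 and DNA replication genes one of -2.02, while the medians of the lists that rose lie at 0.33 or below.

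Matrix genes split by member. Of 32 collagen and matrix genes 9 rose, 10 fell and 13 did not pass, and adjusted over the list alone 12 rose and 11 fell. The list median of 0.01 and mean of -0.04 differ in sign, the median was -0.01 with median-ratio scaling and -0.03 with a fixed sum or with quantile normalization, and the direction tested was down (camera, Benjamini-Hochberg adjusted p = 0.946). COL5A1, a collagen that nucleates fibrils, fell from 1093 ± 64.1 to 442 ± 26.2 FPKM (SD, n = 3 each), and the matrix glycoprotein TNC fell by 1.08 log2 units. The small proteoglycan FMOD rose from 54.4 ± 1.95 to 77.3 ± 2.78 FPKM, and COL3A1 rose by 0.29. Values were -0.22 for COL1A1, 0.01 for COL1A2 and 0.06 for FN1, none of which passed.

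Genes of matrix degradation moved both ways. Of 25 genes of a list that holds proteases and also inhibitors and a receptor of them 14 rose, 4 fell and 7 did not pass, and 15 rose and 5 fell adjusted over the list alone, but the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.117). The cathepsin CTSS (0.67), the surface protease FAP (0.55), MMP3 (0.49), MMP2 (0.38) and MMP14 (0.35) rose. Without siNUSAP c MMP3 stood at 0.40 and was no longer called (limma, Benjamini-Hochberg adjusted p = 0.0613; 0.00522 to 0.0677 over the alternatives), and MMP2 was not called with no filter (0.066) or quantile normalization (0.0754; 0.000658 to 0.0754). With quantile normalization MMP2 stood at 0.18. MMP1, the interstitial collagenase, had a value of 0.03 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.831). ADAM12 fell from 417 ± 27.1 to 154 ± 4.31 FPKM and the metalloproteinase inhibitor TIMP3 from 1164 ± 40.7 to 569 ± 8.38 FPKM (SD, n = 3 each), and the 3' UTRs of both hold ACACACA at 3 places.

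Adhesion receptors included several falls. Of 27 integrin and adhesion genes 7 fell, 5 rose and 15 did not pass, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.173). The list passed in 1 of 23 alternatives, fry, which sets a list against no change (Benjamini-Hochberg adjusted p = 0.0244). The collagen receptor subunit ITGA11 fell from 196 ± 14.7 to 81.4 ± 4.42 FPKM (SD, n = 3 each), the laminin receptor subunit ITGA6 fell by 1.00 and ITGB3 by 0.56 log2 units. The 3' UTR of ITGA11 holds ACACACA at 10 places.

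Some inflammatory genes rose, and most did not pass. Of 24 cytokine and NF-kB target genes 9 rose, 2 fell and 13 did not pass, and 11 rose and 2 fell adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0433). The call was lost at an adjusted p = 0.234 with an estimated correlation, at 0.153 with FPKM of at least 5, at 0.0771 with the length and GC trend removed, and at 0.0516 without siCTL a and 0.0505 without siNUSAP c, within a range of 0.0273 to 0.234 over the camera alternatives (Benjamini-Hochberg). With that trend removed the list median was 0.22 (quartiles -0.01 and 0.41) against 0.23 (0.01 and 0.41) before, and the median of all genes, with which camera compares a list, was 0.07 against 0.04. The mitochondrial superoxide dismutase SOD2 rose from 197 ± 11.6 to 337 ± 8.5 FPKM (SD, n = 3 each), the alarmin IL33 by 0.41 and the prostaglandin synthase PTGS2 by 0.54 log2 units, while the chemokine CXCL1 fell by 0.69 and the growth factor CSF1 by 0.22. CSF1 was not called with no trend (limma, Benjamini-Hochberg adjusted p = 0.0518) or without siNUSAP a (0.0751) or siNUSAP c (0.07), in a range of 0.00891 to 0.0751 over the alternatives. IL6 (0.49) and CXCL8 (0.15) did not pass. Of 22 interferon-stimulated genes 7 rose, 1 fell and 14 did not pass, and 10 rose and 2 fell adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0371). That call was lost at an adjusted p = 0.222 with an estimated correlation, at 0.153 with FPKM of at least 5, at 0.0771 with the length and GC trend removed, and at 0.0505 without siNUSAP c, within a range of 0.0152 to 0.222 over the camera alternatives (Benjamini-Hochberg). With that trend removed the interferon list median was 0.24 (quartiles 0.03 and 0.38) against 0.21 (0.02 and 0.39) before. IFIT1, an antiviral RNA binder, rose by 0.80 and the signal transducer STAT2 by 0.48 log2 units, while OAS3, which senses double-stranded RNA, fell by 0.91.

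Fibroblast subset markers showed small shifts. Of 15 sublining fibroblast markers 6 rose, none fell and 9 did not pass, and 9 rose adjusted over the list alone (median 0.23; camera, Benjamini-Hochberg adjusted p = 0.00656). The call was lost at an adjusted p = 0.414 with an estimated correlation, in a range of 0.00127 to 0.414 over the alternatives (camera, Benjamini-Hochberg). CADM1 (0.42), ASPN (0.46) and the WNT antagonist SFRP1 (0.24) rose, while THY1 (-0.01) and CXCL12 (0.23) did not pass. Of 9 lining fibroblast markers 3 rose, 1 fell and 5 did not pass, with the same counts adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.63). The hyaluronan synthase HAS2 fell by 0.46, and MMP3 and the lubricin gene PRG4 (0.32) rose. MMP3 was not called without siNUSAP c (limma, Benjamini-Hochberg adjusted p = 0.0613), nor PRG4 without siCTL a (0.0726) or siCTL b (0.0541; 0.000995 to 0.093 over the alternatives).

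Growth factor and transcriptional programmes moved by member. Of 29 growth factor and receptor kinase genes 9 fell, 6 rose and 14 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.309). The receptors FGFR1 (-0.62) and PDGFRB (-0.56) and the growth factor FGF5 (-0.66) fell. Of 24 YAP and TAZ target genes 6 fell, 4 rose and 14 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.403); CDC42EP3 (-0.47), AMOTL1 (-0.55) and IGFBP3 (-0.33) fell. Of 19 TGF-beta target genes 5 rose, 2 fell and 12 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.35). JUNB (0.67), the tetraspanin TSPAN2 (1.18) and ID2 (0.52) rose, and CDKN2B (-0.43) fell. Of 17 mesenchymal transcription factor genes 5 fell, 1 rose and 11 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.309); NFIB (-0.73) and PRRX1 (-0.27) fell and TCF4 rose by 0.30.

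Of 20 WNT pathway genes 3 fell, 2 rose and 15 did not pass, also adjusted over the list alone; the median of 0.01 and the mean of -0.04 differ in sign, the median was -0.01 with median-ratio scaling and -0.03 with a fixed sum, and the direction tested was down (camera, Benjamini-Hochberg adjusted p = 0.884). WNT5B (-0.34) and TCF7 (-0.29) fell, and SFRP1 and the WNT antagonist DKK1 (0.27) rose. TCF7 was not called with no filter (limma, Benjamini-Hochberg adjusted p = 0.0749) or without siCTL b (0.0539), siNUSAP b (0.0538) or siNUSAP c (0.0967), in a range of 0.0199 to 0.0967 over the alternatives. DKK1 was not called with no filter (limma, Benjamini-Hochberg adjusted p = 0.112), with no trend (0.0654), or without siNUSAP a (0.0751) or siNUSAP c (0.108), in a range of 0.00404 to 0.112. Of 7 Notch pathway genes 4 fell, none rose and 3 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0166). The call was lost at an adjusted p = 0.489 with an estimated correlation, at 0.223 with no filter and at 0.0888 with FPKM of at least 5, in a range of 0.00928 to 0.489 over the alternatives (camera, Benjamini-Hochberg). The receptor NOTCH1 fell from 4.35 ± 0.609 to 1.79 ± 0.168 FPKM (SD, n = 3 each), the coactivator MAML1 by 0.54 and the DNA-binding partner RBPJ by 0.29 log2 units. Of 13 RNA interference machinery genes 4 fell, none rose and 9 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0644). The list passed with no filter (camera, Benjamini-Hochberg adjusted p = 0.0152), without siCTL a (0.0353) and without siNUSAP b (0.0495), in a range of 0.0152 to 0.632 over the camera alternatives. XPO5 (-0.35), DGCR8 (-0.32) and DROSHA (-0.33), which make and export microRNA precursors, fell. DROSHA was not called without siNUSAP a (limma, Benjamini-Hochberg adjusted p = 0.0601; 0.00856 to 0.0601 over the alternatives).

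Some ribosomal protein and mitochondrial genome genes rose, and most did not pass. Of 30 ribosomal protein genes 10 rose, RPL7 (-0.29) fell and 19 did not pass over all genes, and 19 rose and 1 fell adjusted over the list alone (median 0.23; camera, Benjamini-Hochberg adjusted p = 7.68e-05). Of 13 mitochondrial genome genes 5 rose, none fell and 8 did not pass, also adjusted over the list alone (median 0.30; camera, Benjamini-Hochberg adjusted p = 0.00656). Each call was lost at an adjusted p = 0.65 with an estimated correlation, the highest over the alternatives, against a lowest of 1.05e-06 for ribosomal protein genes and 0.000409 for mitochondrial genome genes (camera, Benjamini-Hochberg). Fry gave adjusted p-values of 0.116 and 0.137 (Benjamini-Hochberg), and quantile normalization ended the mitochondrial call at 0.367 with a median of 0.15 and 0 members rising. Without siCTL c the medians were 0.15 for ribosomal protein genes, 11 of them higher, and 0.16 for mitochondrial genome genes, 4 of them higher. RPL15 (0.25), RPL13 (0.25) and RPL4 (0.25) and MT-CO1 (0.43), MT-CO2 (0.52) and MT-CO3 (0.34) are uncertain as single genes, since both families have near-identical copies elsewhere in the genome. Without siNUSAP c none of these 6 genes was called (limma, Benjamini-Hochberg adjusted p 0.0515 to 0.123), without siNUSAP a neither RPL13 (0.0674), RPL4 (0.0847), MT-CO1 (0.103) nor MT-CO2 (0.0764), and without siCTL b not RPL4 (0.0526). RPL7 was not called with no filter (limma, Benjamini-Hochberg adjusted p = 0.111), with no trend (0.0595), or without siCTL a (0.0884), siCTL b (0.0801), siNUSAP a (0.0594) or siNUSAP b (0.0896), in a range of 0.00086 to 0.111 over the alternatives.

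Markers of other joint cell types were few among the tested genes. CD74 (0.42) was the single macrophage marker of 2 tested that rose, and CD14 (0.37) passed with it adjusted over the list alone. None of 3 lymphocyte markers passed on either scale, with CD4 at 0.20 (limma, Benjamini-Hochberg adjusted p = 0.318). Of 4 endothelial markers ROBO4 rose (0.30) and TEK fell (-0.18), of 4 cartilage markers COMP rose (0.17), and 2 did not pass in the former list and 3 in the latter, also adjusted over the list alone. TEK and COMP were each not called without any 1 of the libraries other than siCTL c (limma, Benjamini-Hochberg adjusted p 0.0628 to 0.0891 for TEK and 0.0567 to 0.112 for COMP; up to 0.469 and 0.133 over the alternatives). With the length and GC trend removed TEK stood at -0.0533 (limma, Benjamini-Hochberg adjusted p = 0.469). ROBO4 was not called without any 1 of the 6 libraries (limma, Benjamini-Hochberg adjusted p 0.0573, without siCTL c, to 0.105), with median-ratio scaling (0.0521), with a fixed sum (0.0796) or with no filter (0.113), in a range of 0.00972 to 0.113 over the alternatives. Neither PPARG (0.07), the only adipocyte marker tested, nor any of 3 epithelial markers, with CLDN4 at 0.36, passed on either scale. Of 6 mural cell markers 2 rose, the actin ACTA2 (0.36) and the potassium channel KCNJ8 (0.66), while the proteoglycan CSPG4 fell by 0.90 and 3 did not pass, also adjusted over the list alone. ACTA2 was not called without siNUSAP a (limma, Benjamini-Hochberg adjusted p = 0.0506) or siNUSAP c (0.057), nor KCNJ8 without siCTL b (0.0511), siNUSAP a (0.06) or siNUSAP b (0.0668), the highest over the alternatives for each. The mural list had a median of 0.04 and a mean of -0.03, and the direction tested was down (camera, Benjamini-Hochberg adjusted p = 0.884).

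The libraries separated by group. Pearson's r across genes was 0.9898 to 0.9944 within a group and 0.9617 to 0.9693 between groups; genes are not independent replicates. The first principal component held 73.3% of the variance and parted the groups. The second held 10.7% and set siCTL c (18.1) against siCTL a (-10.2) and b (-9.55). Its difference from the mean of a and b rose with gene length across genes (Spearman's correlation 0.363), from a median of -0.14 log2 units in the shortest of 4 length classes (median length 843 bases) to 0.08 in the longest (2855 bases). Across genes the log2 fold change had a Spearman correlation with length of -0.187, and of -0.0895 without siCTL c.

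Fold changes also differed with the content of the 3' UTR, a comparison chosen after the fold changes were seen. ACACACA and CAGTACC were picked for their tie to lower fold changes in these same genes. The order of the medians is therefore no separate support, and the medians are not adjusted for 3' UTR length. Outside the mitosis, replication and repair lists, genes with neither ACACACA nor CAGTACC in the 3' UTR had a median log2 fold change of 0.06 (8580 genes, 13.2% lower and 16.4% higher). Genes with ACACACA alone had a median of -0.05 (1805 genes, 25.5% lower), genes with CAGTACC alone one of -0.07 (500 genes, 29% lower) and genes with both one of -0.16 (270 genes, 40.4% lower and 9.63% higher). ACACACA stands in 2075 of the 11155 3' UTRs searched. COL5A1, BCL2, ITGA6, AMOTL1, NFIB and MAML1 are named falling genes with both words. Other named falling genes hold a single word, such as INHBA with ACACACA and TNC and RBPJ with CAGTACC, and not each is marked in the text. CDKN1A holds both words too and rose, and KLHL24, TSPAN2, CADM1, SFRP1 and CST2 hold ACACACA and rose.

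**Figure D3:**
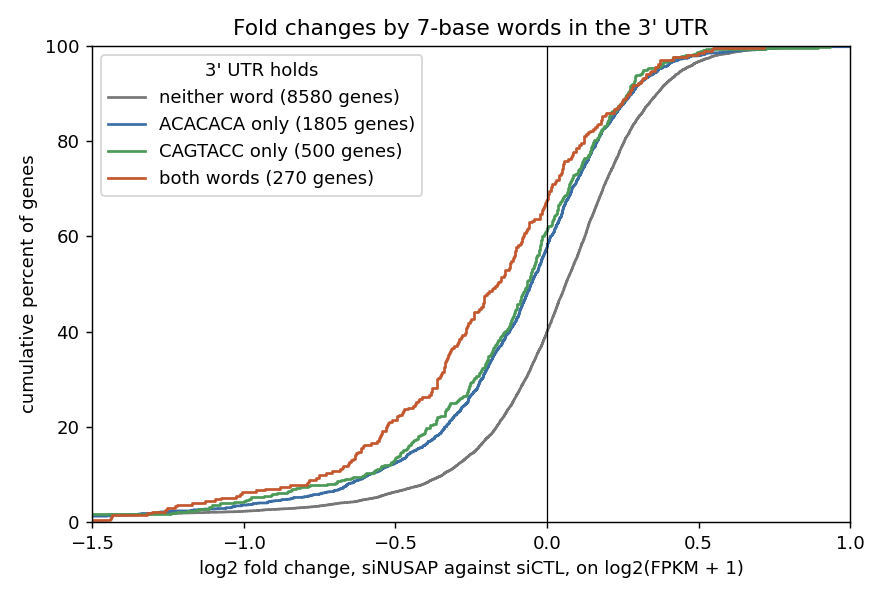
Cumulative percent of genes by log2 fold change, siNUSAP against siCTL, for genes outside the mitosis, replication and repair lists, with 1 line for each content of the 3' UTR. The line for genes with both words (270 genes, median -0.16) lies to the left of that for genes with neither (8580 genes, median 0.06). The words, ACACACA and CAGTACC, were picked from these same fold changes.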

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

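The removal of the length and GC trend and the test of scaling were chosen after the results were seen. Genes changed numbered 3859, and 2711 to 4674 over the alternatives. NUSAP1 stayed between -6.69, with a pseudocount of 0.1, and -4.53, and passed limma in all 18 alternatives (Benjamini-Hochberg adjusted p 2.55e-09 to 1.35e-05); its siNUSAP values rest on 2, 14 and 5 fragments, so depth limits how much of it remained. Genes higher moved from 1840 to 1125 with no filter, where 27422 genes were tested. Leaving out 1 library in turn gave 2752 to 3964 genes changed, 1175 to 1906 higher, 1571 to 2058 lower, 413 to 431 changed at least 2-fold, 12 to 15 lists called and a NUSAP1 value of -4.73 to -4.53; without siNUSAP a and without siNUSAP c the higher genes numbered 1223 and 1175, and with 1 library fewer the test has fewer samples. Genes at least 2-fold higher numbered 16, and 58 and 30 with pseudocounts of 0.1 and 0.5, 78 with voom on recovered counts, 6 at an FPKM of at least 5, 7 among protein-coding genes, and 25 and 31 without siCTL a and siCTL b. With the length and GC trend removed 2724 genes were higher and 1896 lower, 59% higher against 47.7%, and with FPKM rescaled to a fixed sum 1370 and 2232 (38%), by the median ratio 1594 and 2176 (42.3%), and with quantile normalization 2349 and 1839 (56.1%); the cause was not tested. Voom called 4292 genes, 3745 of them shared with the 3859.

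Lists called fell from 14 to 4 with an estimated correlation. The interferon (-0.0337) and cytokine (0.0031) lists lost their call with an estimate below the preset. DNA repair genes (-0.0296) went from an adjusted p = 1.97e-17 to 0.00655 (camera, Benjamini-Hochberg). For these lists, correlation between members is argued against as the cause. The other reported lists that lost their call had estimates above the preset, 0.0409 (oncogene and tumour suppressor genes) to 0.863 (mitochondrial genome genes). Since the adjusted p of DNA repair genes rose with an estimate below the preset, these losses cannot be put down to correlation alone. Their cause was not tested. Fry called 17. Of 2079 values of the other 116 named genes, 2009 kept direction and side of the threshold, 69 kept direction and lost the call, and 1 reversed: PPARG, which passed in no setting, was -0.016 without siCTL c and -0.016 to 0.14 over the libraries left out; the cause was not tested. The 14 genes that lost a call were ACTA2, COMP, DROSHA, KCNJ8, MMP3, MT-CO1, MT-CO2, MT-CO3, PRG4, RPL13, RPL15, RPL4, TCF7 and TEK, with COMP lost in 11 of 18 alternatives and TEK in 9. Calls lost numbered 3 without siCTL a, 6 without siCTL b, 9 without siNUSAP a, 4 without siNUSAP b, 11 without siNUSAP c, 0 without siCTL c, 12 with no filter and 7 with quantile normalization. Of genes outside the naming rule that did not pass, COL1A1 passed in 4 alternatives, CXCL12 in 6, IL6 in 3 and FN1 in 1.

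The labels do not say whether the letters a, b and c pair the samples, and the values show no sign of it: deviations from the group means correlated at 0.033, -0.111 and -0.187, and not every sample correlated best with its own letter (siCTL c with siNUSAP b, 0.206). With the letters as a block 2837 genes changed, 2797 of them among the 3859, and 3713 with the length and GC trend removed as well. Outside the naming rule, the block ended the calls of MDM2 (limma, Benjamini-Hochberg adjusted p = 0.0591), CSF1 (0.0658), RPL7 (0.0681), DKK1 (0.0902), ROBO4 (0.0926) and PFKP (0.113). Of named genes 9 lost their call with the block, 0 ribosomal protein and 0 mitochondrial genome genes were called (limma, Benjamini-Hochberg; 10 and 5 without it), and the cytokine list had an adjusted p = 0.0537 (camera, Benjamini-Hochberg), in a range of 0.0273 to 0.234 over the camera alternatives.

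The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05: the real split gave 3859 genes, so that 1 of the 10 gave as many, and the highest other gave 0 (limma, Benjamini-Hochberg; 128 to 387 genes at an unadjusted p under 0.05 in the others). Each of the other splits mixed libraries of both groups, so the group difference entered its spread. Its low count was thus set in advance and gives no measure of what chance yields. Against scaling as the whole source of the fall of mitosis and DNA replication genes, their median was -2.82 or lower under each of 3 rescalings, and against gene length and GC content, the median left after that trend was -2.76.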

Other observations

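The tests of a growth difference, of an effect through CCND1 and of depth were chosen after the results they bear on were seen, and the depth test replaced an earlier chi-square between single libraries, which sets their whole spread against counting noise. The senescence and histone lists held members that rose and members that fell. Of 17 senescence-associated genes, secreted and intracellular, 6 rose, 6 fell and 5 did not pass, and 8 rose and 6 fell adjusted over the list alone; the median of 0.04 and mean of -0.16 differ in sign, and the direction tested was down (camera, Benjamini-Hochberg adjusted p = 0.867; fry, which sets a list against no change, 0.000892). The nuclear lamina gene LMNB1 fell from 35.3 ± 0.894 to 2.98 ± 0.0674 FPKM (SD, n = 3 each) and the activin subunit INHBA fell by 1.24 log2 units. Of 13 histone genes 6 rose, 3 fell and 4 did not pass, and 7 rose and 3 fell adjusted over the list alone (median 0.29; camera, Benjamini-Hochberg adjusted p = 0.345). The variants H2AZ1 (-1.59) and H2AZ2 (-0.69) fell and H2AC6 rose by 0.51, and all are uncertain as single genes, since histones have near-identical copies.

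Stress and metabolic lists held some changed members, nearly all of them changed less than 2-fold. Of 25 endoplasmic reticulum stress genes 10 fell, 2 rose and 13 did not pass, and 11 fell and 3 rose adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.017). That call was lost at an adjusted p = 0.489 with an estimated correlation, in a range of 0.00112 to 0.489 over the alternatives (camera, Benjamini-Hochberg). EDEM1 (-1.16), the serine synthesis enzyme PHGDH (-0.47) and TRIB3 (-0.61) led it, and DNAJB9 (0.41) and HERPUD1 (0.24) rose. HERPUD1 was not called without siCTL a (limma, Benjamini-Hochberg adjusted p = 0.0589), siNUSAP b (0.0637) or siNUSAP c (0.0659), in a range of 0.0126 to 0.0659 over the alternatives. Of 27 hypoxia and glycolysis genes 4 rose, 1 fell and 22 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.173); the hexokinase HK2 rose from 15.2 ± 0.578 to 28.6 ± 0.708 FPKM (SD, n = 3 each), P4HA1 by 0.33 and SLC2A3 by 0.42 log2 units, and PFKP fell by 0.16. PFKP was not called with no filter (limma, Benjamini-Hochberg adjusted p = 0.0524), with no trend (0.0788) or without any 1 of the libraries other than siCTL c (0.0672 to 0.107), in a range of 0.00755 to 0.113 over the alternatives. Of 21 oxidative stress genes 5 rose, 1 fell and 15 did not pass, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.339), with SOD2 (0.78) and SQSTM1 (0.44) rising and SLC7A11 falling by 0.49. Of 24 sterol synthesis genes 5 rose, 5 fell and 14 did not pass, and 6 rose and 7 fell adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.867); MSMO1 rose by 0.65, and DHCR7 fell by 0.49. Of 21 immediate early and heat shock genes 4 rose, 5 fell and 12 did not pass, and 5 rose and 5 fell adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.867), with JUNB rising and HSPA8 (-0.44) and HSPD1 (-0.27) falling.

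Genes lower in siNUSAP outside the cell cycle lists may include off-targets of the siRNA pool, which can lower transcripts whose 3' UTR matches the seed of a guide strand. Gene length and GC content explained a share of 0.0225 of the variance of fold changes there, and 0.85 of 1906 lower genes kept a residual below -0.2, which argues against that source. The word ACACACA was tied to lower fold changes with t = -13.21, against a lowest t of -4.77 in 100 shuffles, the overlapping word CACACAA followed with -12.09, and CAGTACC, the first word of another family, with -10.56, while the reverse complements of ACACACA and CAGTACC, TGTGTGT (-0.88) and GGTACTG (-0.1), were not. The first words of both families, 2 of 2, stand in the sense strand of all 6 protein-coding NUSAP1 transcripts of GENCODE 29, as a guide against NUSAP1 would need, and 2.33% of 2445 transcripts of similar length hold both; of the 16 leading words, which include TTTTTTA (-6.79) and AACGGAA (-5.22) of neither family, 9 stand in the longest NUSAP1 transcript, and others, CACACAC (-9.28) among them, do not. A candidate explanation is therefore guides of the pool whose seeds pair with these words. The siRNA sequences are not given in the sources used here, and a link to any single gene is untested. Outside the mitosis, replication and repair lists, 301 searched genes were lower at least 2-fold. Of them 39.2% held ACACACA, CACACAA, CAGTACC or AGTACCT, against 31.2% of all searched, though these words were picked from the same fold changes. Those lists do not hold every cell division gene: the spindle motor KIFC1 (-3.84) lies outside them and holds none of these words. Loss of NUSAP1 itself stays open for the lower genes too.

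Direct repression through ACACACA, CACACAA, CAGTACC or AGTACCT is argued against as the source of the fall of mitosis and DNA replication genes. The 51 members without these words in the 3' UTR had a median of -2.84, that of all 59. The word search left these genes out and the siRNA sequences are not given in the sources used here. Direct repression through other words was therefore not tested. An indirect effect through CCND1, whose 3' UTR holds ACACACA at 4 places, could not be told apart from loss of NUSAP1, since CCND1 was at -2.08 or lower in every setting run. An effect through CDK6 (-1.08), whose 3' UTR holds ACACACA too, was not tested. A growth difference between the cultures apart from the siRNA cannot be told apart either, because no label gives a culture or day shared by the groups within which to compare them. The gap of 2.67 log2 units in the mean of these genes, from the lowest siCTL library to the highest siNUSAP library, does not decide it. Loss of NUSAP1 itself stays open as the biological explanation.

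The control library siCTL c stood apart from siCTL a and b. Sequencing depth is argued against, since at equal depth at least 0.931 of the gap in correlation was kept in 10 thinnings. Gene length and GC content explained a share of 0.13 of the variance of its difference, against 0.00185 for siCTL a and b, and 0.776 of the gap in correlation was kept with that trend removed, so a part may come from it, and whether the rest does cannot be told apart from other differences between libraries. No biological explanation was tested.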
